A study of Mus musculus with 29 samples.

How the data were processed

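The series holds 29 libraries of polyA RNA bound to tagged ribosomes (translating ribosome affinity purification, TRAP), each from the cortex of 1 mouse aged 6 months. Microglia carried an eGFP-L10a ribosomal tag switched on by Cx3cr1-CreERT2 after 6 doses of 100 mg/kg tamoxifen. The labels put the libraries in 7 groups, and each library also has a sex and a batch (1 or 2). Libraries were made with the SMART-Seq mRNA LP kit.

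Per the submitters' processing notes, reads were handled with Trim Galore, HISAT2 2.2.1 and featureCounts 2.0.3 on the mm10 genome. The annotation, the strandedness and the handling of reads with several matches are not stated. The first deposited table holds raw counts for 22327 gene symbols in each of the 29 libraries. The second deposited table holds RPKM values, which are counts scaled to the library's total and to a length per gene. That length was within 0.1% of the whole gene span, introns included, for 86.3% of the 21439 symbols found in GENCODE. Its column names end in "counts" although its values are RPKM. Library totals ran from 1.662 to 31.998 M counts with a median of 6.049 M, and no 2 libraries of the same group were copies of each other. Reads were not marked with molecular identifiers, so every spread below covers sequencing and animals together, while intervals or floors from counts alone cover counting error only.

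Differences between groups were tested on the count table in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group (minimum count 10, minimum total 15), which left 16074 genes. Counts were scaled with TMM factors, and 1 model with group, batch and labelled sex was fitted to all 29 libraries (20 residual degrees of freedom). Each comparison used edgeR's quasi-likelihood F-test, two-sided and robust, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05, without a minimum fold. CPM (counts scaled to library size) printed beside fold changes are TMM-scaled, while CPM of Malat1 and of the targeted genes given per group are per library total. Fold changes are log2 values with their standard error (SE). Coordinates are mm10 positions from GENCODE release M21, in which 21439 of the 22327 symbols were found.

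The 8 pairwise comparisons and 2 differences between differences were fixed before the data were examined. So were 30 gene lists, among them targets of ATF4 and the integrated stress response, tRNA synthetases, ER chaperones, homeostatic and disease-associated microglial genes, and interferon, antigen presentation, inflammatory, cholesterol, fatty acid, lipid droplet, lysosome, complement, immediate-early, glycolysis, oxidative stress, cell cycle, ribosomal protein, oxidative phosphorylation and mitochondrially encoded genes. Markers of neurons, astrocytes, oligodendrocytes, their precursors, endothelial and mural cells, border macrophages, monocytes and neutrophils, and lymphocytes were listed too, with 1 list of the genes the mouse lines target. Each list was tested with camera from limma 3.58.1 at the preset correlation of 0.01, Benjamini-Hochberg adjusted over the 30 lists of a comparison. Camera with an estimated correlation and fry were run beside it, and the number of changed members was also counted with p adjusted over the list alone. Shares of counts in a list were compared between groups with exact permutation tests, two-sided, in a family of 88 tests. Mean levels of 7 lists per library were compared the same way in a family of 42 tests.

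Named genes followed a rule fixed at the same time. For each pairwise comparison it took the 8 changed genes with the smallest p in each direction, with an absolute log2 fold change of at least 0.5 and a mean log2 CPM of at least 1, and up to 4 changed members of each list. Unnamed gene models and sex-chromosome genes were left out, and the targeted genes were given in every group. The genes printed below were taken from these, with preference for genes whose call did not rest on 1 library. Malat1 and Gm26561 are printed although they fall outside the rule.

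The procedure was tested on simulated data made from the fitted means and spreads. With group sizes as in the study it called 59.1% to 75.8% of genes changed 4-fold, 4.48% to 25.4% of genes changed 2-fold and 1.49% to 2.99% of genes changed 1.5-fold. False calls numbered 0 to 4 in a comparison. The simulated counts had 1 spread per gene shared by all groups, as the model assumes. False calls in the real libraries, whose spread can differ between groups, were not measured this way.

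Alternatives were other size factors (RLE, upper quartile), no or a stricter low-count filter, models without sex or batch, batch 1 alone, only the groups compared, a replicate block, limma-voom, DESeq2 1.42.0, limma-trend on the RPKM table, and every library of the compared groups left out in turn. Alternatives added after the data were seen were sex taken from Y-linked reads, the fit without 3 libraries rich in neuron markers, the 4 groups without the iPKR construct alone, batch 2 alone, libraries thinned to equal depth, and the interaction without 2 of the 5xFAD TRAP libraries. For each comparison other splits of its libraries were also refitted, at most 60 of them, and again with the batch numbers of each group kept. No library was left out of the main comparisons.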

Results

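RNA bound to tagged ribosomes was sequenced from the cortex of 29 mice to follow the integrated stress response of microglia, in which phosphorylation of the translation factor eIF2α (gene Eif2s1) lowers general translation and raises the transcription factor ATF4. The TRAP group (n = 5) carried the ribosomal tag alone. Eif2A mice (n = 4) carried an Eif2s1 allele whose product cannot be phosphorylated, with the tag per the sample labels, while the series description leaves the tag out of both Eif2A genotypes. Mice with the iPKR construct carried the tag joined to NS3 and an inducible form of the eIF2α kinase PKR. They received VEGF (1 µg/kg) with vehicle (n = 4) or with 5 mg/kg ASV (asunaprevir, an inhibitor of the NS3 protease; n = 5) for 4 weeks. The 5xFAD transgenes, which give amyloid plaques, were combined with the tag alone (5xFAD TRAP, n = 4, given VEGF and ASV), with Eif2A (n = 3, not given ASV) and with iPKR (n = 4, given VEGF and ASV). Totals per library were 3.511 to 10.864 M counts in TRAP, 2.052 to 4.903 M in 5xFAD TRAP, 4.035 to 21.367 M in Eif2A and 7.059 to 7.629 M in 5xFAD Eif2A. They were 2.904 to 31.998 M in iPKR vehicle, 1.75 to 6.376 M in iPKR ASV and 1.662 to 12.496 M in 5xFAD iPKR.

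Libraries with the iPKR construct held much less RNA of microglial genes than the others. The 19 homeostatic microglial genes, such as Csf1r, took 6.18% ± 1.13 of counts (SD, n = 5) in TRAP and 0.513% ± 0.200 (n = 4) in iPKR vehicle. They took 0.605% ± 0.535 (n = 5) in iPKR ASV and 1.11% ± 0.783 (n = 4) in 5xFAD iPKR. The 13 neuron markers took 0.154% ± 0.022 of counts in TRAP (n = 5), 0.993% ± 0.054 in iPKR vehicle (n = 4), 1.46% ± 0.677 in iPKR ASV (n = 5) and 2.11% ± 1.71 in 5xFAD iPKR (n = 4). For the share of homeostatic genes, iPKR vehicle against TRAP gave p = 0.01587 in an exact permutation test, adjusted p = 0.1164 over 88 tests. This p is the smallest that the test can give for 5 against 4 libraries. The shares did not overlap, at 4.67% or more in TRAP and 0.78% or less in iPKR vehicle. Cx3cr1, the gene that drives the Cre, was at 504 ± 278 CPM (not TMM-scaled) in TRAP (n = 5) and 32.1 ± 22.2 CPM in iPKR vehicle (n = 4). These groups overlapped, since TRAP replicate 2, at 15.68 CPM, lay below iPKR vehicle replicates 2, 3 and 4 (49.57, 35.3 and 43.65 CPM).

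**Figure D1:**
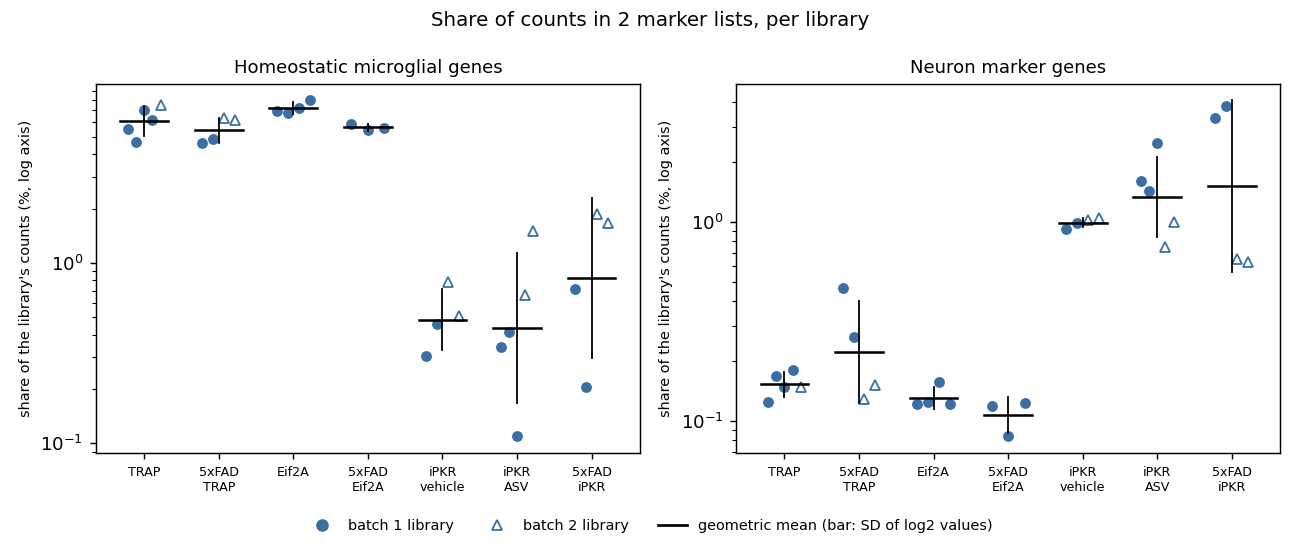
Share of each library's counts in homeostatic microglial genes (left) and neuron marker genes (right), in percent on a log axis; circles are batch 1 and triangles batch 2 libraries, lines are geometric means and bars 1 SD of log2 values. Every iPKR library lies below every other library for homeostatic genes, with group means of 6.18% in TRAP and 0.513% in iPKR vehicle.

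The comparison of iPKR vehicle with TRAP showed what went with the construct, VEGF and vehicle without the drug. All 19 homeostatic genes fell (19 also when adjusted over the list alone), with a median log2 fold change of -4.06. Csf1r, which encodes a growth factor receptor that microglia need, fell from 2250 ± 149.6 to 144.7 ± 35.2 CPM (log2 fold change -3.93 ± 0.29 SE, n = 5 and 4, adjusted p = 6.406e-11). The neuronal splicing factor Rbfox3 rose from 64.2 ± 14.8 to 333.7 ± 49.6 CPM (log2 fold change 2.33 ± 0.20 SE), and all 13 neuron markers rose (13 over the list alone), with a median of 2.52. Of the other cell types, 9 of 10 astrocyte markers (9 over the list alone), 8 of 12 oligodendrocyte markers (9), 4 of 6 precursor markers (4), 3 of 11 endothelial markers (3) and 4 of 8 mural markers (3) rose. Border macrophage markers fell in 8 of 9 (8 over the list alone), and 68 of 74 ribosomal protein genes fell (69), with a median of -1.65. Among the 2 lymphocyte markers 1 rose and 1 fell. The nuclear RNA Malat1, which falls outside the naming rule, rose from 136.8 ± 74.4 to 1156 ± 321 CPM (not TMM-scaled, log2 fold change from the TMM-scaled model 2.21 ± 0.54 SE). Of the mitochondrially encoded genes 6 of 7 rose (7 over the list alone). Both bear on whether all of this RNA was bound to ribosomes. Over all genes edgeR's quasi-likelihood test called 8695 of 16074, 4605 higher and 4090 lower, and within batch 1 alone it called 8185, while batch 2 holds only 1 TRAP library. Camera called the homeostatic list (adjusted p = 1.781e-16) and the neuron list (6.96e-09), but with an estimated correlation these were adjusted p = 0.07506 and adjusted p = 0.1062. Eif2s1 fell in this comparison by 1.08 on the log2 scale (adjusted p = 0.00035).

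The effect of 5xFAD was asked first on the plain tag, where the 5xFAD TRAP mice also received VEGF and ASV and the TRAP mice did not. Disease-associated microglial genes, known to rise around amyloid plaques, rose in 20 of 29 members (25 when adjusted over the list alone), with a median log2 fold change of 2.03. Cst7, a cathepsin inhibitor (chromosome 2, 150570415 to 150578944), rose from 54.1 ± 23.4 to 2098 ± 401 CPM (SD, n = 5 and 4; log2 fold change 5.34 ± 0.55 SE, adjusted p = 1.073e-06). The lipoprotein lipase gene Lpl rose by 5.07 ± 0.49 (adjusted p = 5.102e-07) and the fatty acid carrier Fabp5 by 3.33 ± 0.36 (adjusted p = 2.515e-06). The chemokine gene Ccl3 rose by 3.84 ± 0.51, with 2 of 16 inflammatory genes called higher (3 over the list alone). Among the targeted genes, Thy1, whose promoter drives the 5xFAD transgenes, rose by 2.24 ± 0.52 (adjusted p = 0.02934), a call lost without any 1 of 7 of the 9 libraries (highest adjusted p = 0.135). App (1.15 ± 0.50) did not pass. The list of 12 targeted genes had a median of 0.31, with 1 called higher (1 over the list alone) and camera adjusted p = 0.001746, and adjusted p = 0.0666 with an estimated correlation.

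Cholesterol synthesis genes rose in 5 of 21 members (13 over the list alone), with a median of 1.13, and the sterol desaturase gene Sc5d rose by 1.59 ± 0.30. Lysosomal genes rose in 7 of 22 (13 over the list alone), among them the protease gene Ctsa from 586.6 ± 132 to 1374 ± 207 CPM (log2 fold change 1.29 ± 0.20 SE, n = 5 and 4). Glycolysis genes rose in 2 of 18 (13 over the list alone), with a median of 0.96. The disease-associated, cholesterol, lysosome and glycolysis lists were called by camera at preset and estimated correlation (adjusted p = 4.611e-05, 0.01155, 0.004857 and 0.02187 with an estimated correlation). Of the 31 ATF4 and stress response targets, 1 rose (3 over the list alone) and 1 fell (2). The serine synthesis gene Psat1 rose from 70.95 ± 18.4 to 255.1 ± 115.5 CPM (log2 fold change 2.13 ± 0.30 SE), and the growth inhibitor gene Ddit4 fell by 3.05 on the log2 scale, a call lost without 5xFAD TRAP replicate 2 (adjusted p = 0.0781). The list as a whole had a median of -0.12 and a mean of -0.02, with camera's direction up (adjusted p = 0.522). Mitochondrially encoded genes had a median of -1.07 with no member called (4 lower over the list alone), but the 5xFAD TRAP libraries parted by batch. Their levels relative to the TRAP mean were -2.17 and -1.08 in batch 1 and 1.08 and 0.69 in batch 2, where the highest TRAP library was at 0.57. Neuron markers had a median of 0.54 with 1 of 13 called higher (2 over the list alone), at levels of 0.87 and 0.38 in 5xFAD TRAP replicates 1 and 2 and 0.18 and 0.13 in replicates 3 and 4. Both lists were called by camera (adjusted p = 2.001e-05 and 0.0003705), with adjusted p = 0.181 and adjusted p = 0.2902 with an estimated correlation. In all 127 genes changed, 114 higher and 13 lower, and batch 1 alone gave 174, while batch 2 holds only 1 TRAP library. The number was 82 without TRAP replicate 1, 70 without 5xFAD TRAP replicate 1 and 53 without 5xFAD TRAP replicate 2, and DESeq2 called 729, of which 280 were higher. It was 958 with the 4 groups without iPKR in the model and 749 with only these 2 groups.

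**Figure D2:**
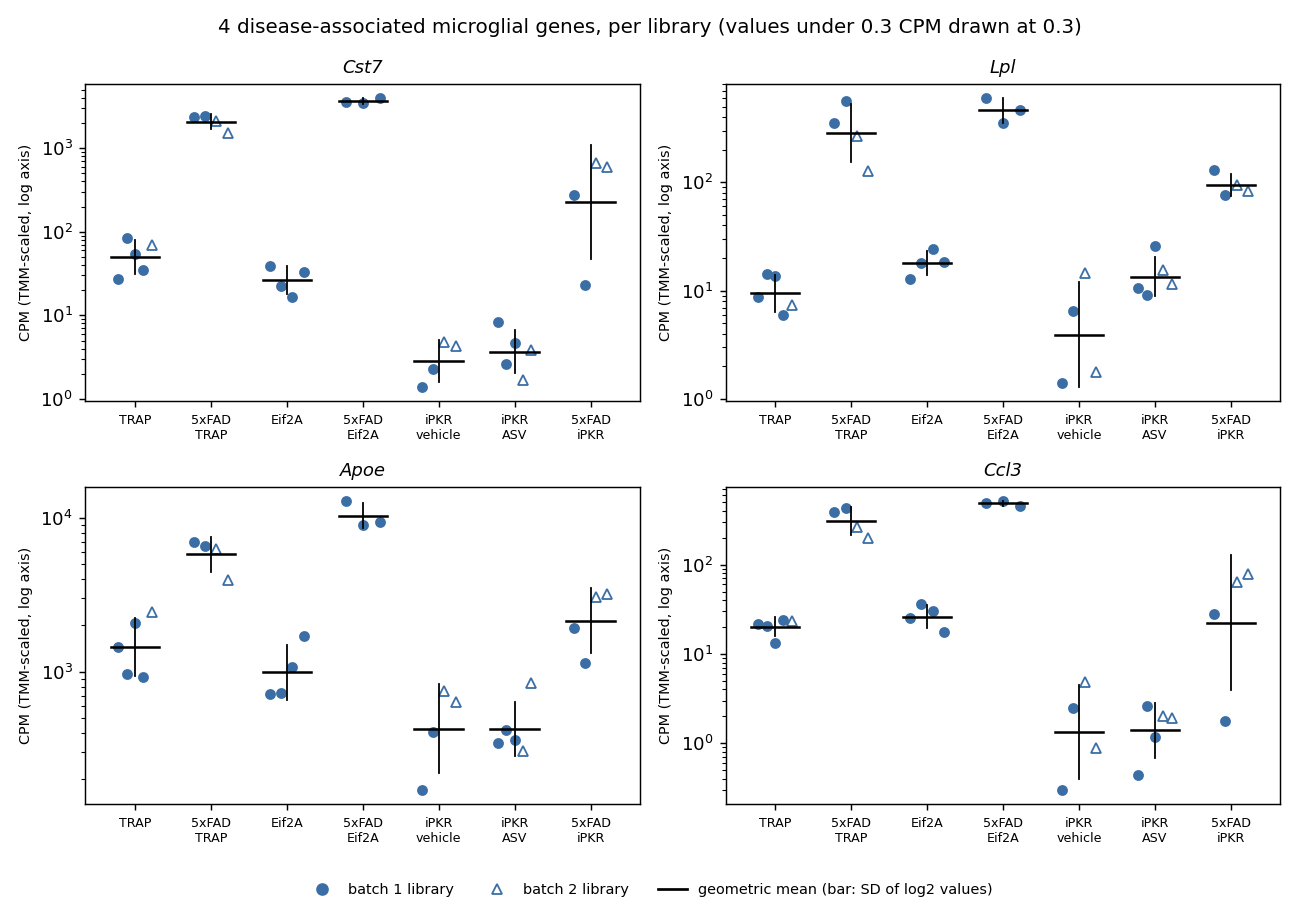
TMM-scaled CPM per library (log axis) of Cst7, Lpl, Apoe and Ccl3 in the 7 groups, with circles for batch 1, triangles for batch 2, lines for geometric means and bars for 1 SD of log2 values. For Cst7 the 5xFAD TRAP mean was 2098 CPM against 54.1 in TRAP, and the 5xFAD Eif2A mean 3679 CPM against 27.9 in Eif2A.

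The same question was put on the Eif2A background, where neither group had ASV and all 7 libraries were in batch 1. Cst7 rose from 27.9 ± 10.2 to 3679 ± 269 CPM (SD, n = 4 and 3; log2 fold change 7.22 ± 0.66 SE, adjusted p = 2.998e-07). Disease-associated genes rose in 24 of 29 members (26 over the list alone), with a median of 2.89, among them the lipid carrier gene Apoe (3.39 ± 0.38) and the protease gene Ctsb (2.41 ± 0.27). Lysosomal genes rose in 12 of 22 (15 over the list alone), with the progranulin gene Grn at 1.60 ± 0.23. Interferon response genes rose in 7 of 19 (14 over the list alone), with a median of 2.24. The calls of Oasl2, Ifitm3, Ifit2 and Irf7 were each lost without 5xFAD Eif2A replicate 1, 5xFAD Eif2A replicate 3 or Eif2A replicate 3 (highest adjusted p = 0.0654, 0.102, 0.133 and 0.123), and that of Irf7 without any of the 7 libraries. Antigen presentation genes rose in 3 of 12 (7 over the list alone), with the class I gene H2-D1 at 2.05 ± 0.42. ER chaperones, which fold secreted proteins, rose in 2 of 18 (10 over the list alone), with Pdia3 at 1.29 ± 0.25. Cholesterol genes rose in 6 of 21 (9 over the list alone), glycolysis genes in 8 of 18 with 1 lower (13 and 1), and lipid droplet genes in 3 of 18 (4), with the sterol acyltransferase gene Soat1 rising from 40.21 ± 2.60 to 130.5 ± 8.09 CPM. Inflammatory genes rose in 3 of 16 (5 over the list alone) and complement genes in 1 of 12 (1).

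Camera called 14 lists here, and 10 of them also with an estimated correlation, from adjusted p = 2.114e-05 for the disease-associated list to 0.04224 for antigen presentation and complement. The oxidative stress list (median 0.17, 1 of 12 higher, 2 over the list alone) and the cell cycle list (0.70, 1 of 18 higher, 1 over the list alone) were called only at the preset correlation, with adjusted p = 0.173 for both with an estimated correlation. Among the ATF4 targets Psat1 rose by 2.17 ± 0.33 and the stress factor gene Atf3 by 2.75 ± 0.62, 2 of 31 in all (2 over the list alone). The Atf3 call was lost without 5xFAD Eif2A replicate 1 (adjusted p = 0.132). The list's median was -0.10, with adjusted p = 0.8344. The kinase gene Prkca fell from 76.2 ± 13.2 to 18.6 ± 2.39 CPM (log2 fold change -2.02 ± 0.26 SE), and the splicing regulator Khdrbs3 fell by 2.90 on the log2 scale. In all 499 genes changed, 334 higher and 165 lower, and with batch 1 alone in the model 716. The number was 2090 with the 4 groups without iPKR in the model, 1664 with only these 2 groups and 1277 with DESeq2. The higher share was 66.9%, with RLE factors 56.8% and with upper-quartile factors 52.5%. The number was 222, 233 and 315 without 5xFAD Eif2A replicates 1, 2 and 3, and 310 and 319 without Eif2A replicates 2 and 4.

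Effects of 5xFAD were alike in direction on both backgrounds. Of the 127 genes changed on the plain tag, 126 had the same sign on Eif2A, with 105 higher in both and 4 lower in both. If calls were independent and equally likely for every gene, 2.369 and 0.1334 would fall together. Both sets of calls share a model and a spread per gene, so these numbers are no measure of chance. Across the 16074 genes, which are not independent replicates, Pearson's r was 0.365 and Spearman's rho 0.425, 1 of 3 such pairs computed. When the difference between the effects was tested itself, edgeR called 1 gene, the unnamed model Gm26561 (3.08 ± 0.48, adjusted p = 0.01041), which falls outside the naming rule and was chosen after its value was seen. At an unadjusted p under 0.05 there were 686 genes, and DESeq2 called 267. The disease-associated list rose more on Eif2A by a median of 0.62, with 24 of 29 members positive and 0 called (0 over the list alone). Camera gave adjusted p = 1.503e-06, but adjusted p = 0.22 with an estimated correlation, and batch 1 alone gave 0.38 (adjusted p = 0.0811). Interferon genes (0.91, 19 of 19 positive), ER chaperones (0.51) and immediate-early genes (0.49) were also called higher at the preset correlation, and neuron markers lower (-0.59), each with adjusted p = 0.22 with an estimated correlation. Interferon levels were uneven, at 2.62 in 5xFAD TRAP replicate 4 against 0.81, 0.01 and 0.58 in replicates 1 to 3, and at 1.02 in TRAP replicate 2 against -0.19 or less in the rest of its group. The number of genes was 0 without TRAP replicate 5, 5xFAD TRAP replicate 1, 5xFAD TRAP replicate 2 or 5xFAD Eif2A replicate 1, 2 without TRAP replicate 3 or 5xFAD TRAP replicate 4, and 3 without Eif2A replicate 4. Only the 5xFAD TRAP mice of these 4 groups had received ASV.

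The third 5xFAD comparison was among mice that all had the iPKR construct, VEGF and ASV, and its RNA cannot be taken as microglial alone. Homeostatic genes took 0.605% of counts in iPKR ASV and 1.11% in 5xFAD iPKR. A different share of microglial RNA was not told apart from an effect of 5xFAD within microglia. Disease-associated genes rose in 21 of 29 members (25 over the list alone), with a median log2 fold change of 2.31, and Cst7 rose from 4.25 ± 2.56 to 392.2 ± 301 CPM (SD, n = 5 and 4; log2 fold change 6.27 ± 0.63 SE, adjusted p = 1.356e-06). Lysosomal genes rose in 13 of 22 (17 over the list alone), with Grn at 2.11 ± 0.21. Antigen presentation genes rose in 9 of 12 (12 over the list alone), with the class II chaperone gene Cd74 at 3.77 ± 0.54. ER chaperones rose in 7 of 18 (14 over the list alone), with Pdia3 at 1.59 ± 0.22, and complement genes in 2 of 12 (5), with the integrin gene Itgb2 at 2.16 ± 0.22. The ATF4 targets had a median of 0.33, with 1 of 31 called higher (4 over the list alone) and 24 positive (adjusted p = 0.02458, and adjusted p = 0.04335 with an estimated correlation). The called member, the serine synthesis gene Phgdh (0.96 ± 0.24), lost its call without any 1 of 7 of the 9 libraries (highest adjusted p = 0.133). Fatty acid genes (1 of 19 higher, 5 over the list alone) and lipid droplet genes (2 of 18, 7 over the list alone) were called as lists at both correlations, with adjusted p = 0.04335 and 0.002981 with an estimated correlation.

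Homeostatic genes, too, rose among the iPKR mice with 5xFAD, in 3 of 19 members (8 over the list alone), with Csf1r at 1.49 ± 0.25 and a list median of 0.89. Camera gave adjusted p = 4.035e-10 for that list, and adjusted p = 0.1135 with an estimated correlation. Endothelial markers were lower, with a median of -1.51, 0 of 11 called (0 over the list alone) and adjusted p = 0.000541 (adjusted p = 0.101 with an estimated correlation). Their share of counts was uneven in iPKR ASV, from 0.0041% to 0.0464%, against 0.0039% to 0.0096% in 5xFAD iPKR. The pre-mRNA splicing gene Prpf8 fell by 1.68 on the log2 scale and the spectrin gene Sptan1 fell by 2.36. In all 277 genes changed, 248 higher and 29 lower, with 454 in batch 1 alone, 124 in batch 2 alone, 10 with only these 2 groups in the model and 845 with DESeq2. The number was 542 without iPKR ASV replicate 3, 472 without 5xFAD iPKR replicate 2, 179 without 5xFAD iPKR replicate 1 and 172 without 5xFAD iPKR replicate 3. Those first 2 libraries and 5xFAD iPKR replicate 1 had the largest shares of neuron markers, and without these 3 the number was 739. Of the 127 genes changed by 5xFAD on the plain tag, 116 had the same sign here and 48 were higher in both, with r = 0.275 and rho = 0.286 across genes. Independent and equally likely calls would give 1.759 higher in both, which for the same reason is no measure of chance.

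**Figure D3:**
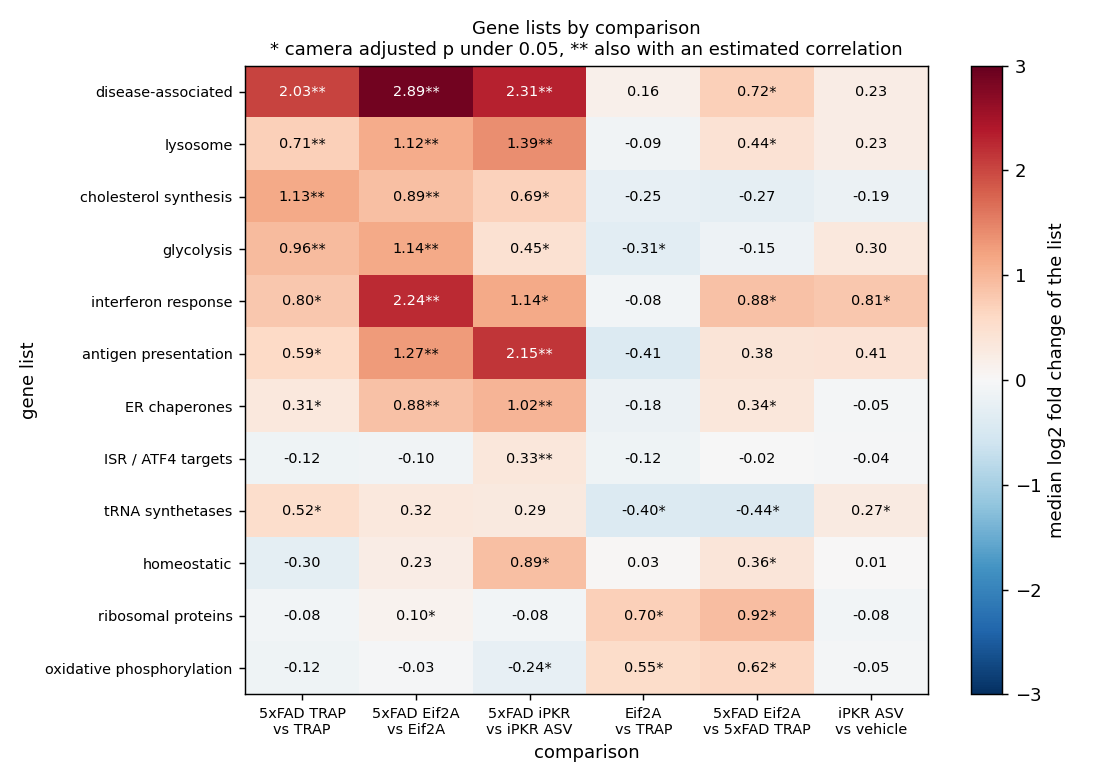
Median log2 fold change of 12 gene lists (vertical axis) in 6 comparisons (horizontal axis), from blue (lower) to red (higher); 1 star marks a camera adjusted p under 0.05 and a double star the same also with an estimated correlation. The disease-associated list had medians of 2.03, 2.89 and 2.31 in the 3 comparisons of 5xFAD, and 0.23 in iPKR ASV against vehicle.

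What the loss of eIF2α phosphorylation does at rest was asked by comparing Eif2A with TRAP mice, both without ASV. The transcript of the targeted gene Eif2s1 (chromosome 12, 78861819 to 78887010) was at 125.6 ± 5.05 CPM (not TMM-scaled) in Eif2A (n = 4) and 119.6 ± 9.88 CPM in TRAP (n = 5), log2 fold change 0.03 ± 0.22. Ribosomal protein genes stood higher as a list, with a median of 0.70, 73 of 74 positive and 0 called (0 over the list alone). Genes of oxidative phosphorylation had a median of 0.55, with 60 of 69 positive and 0 called (0 over the list alone). Aminoacyl-tRNA synthetases, which ATF4 controls, had a median of -0.40, with 1 of 13 positive and 0 called (0 over the list alone). Camera called these lists (adjusted p = 2.394e-36, 2.487e-23 and 0.001211), but with an estimated correlation each call was lost (adjusted p = 0.3434, adjusted p = 0.3434 and adjusted p = 0.683). The tRNA synthetase call was also lost without batch in the model (-0.13, adjusted p = 0.372). Astrocyte markers (median -0.38) and neuron markers (-0.23) were lower in the same comparison, both at adjusted p = 0.0167 and at adjusted p = 0.683 and adjusted p = 0.7072 with an estimated correlation.

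The ATF4 targets did not pass as a list on the Eif2A background, with a median of -0.12, 0 of 31 called (0 over the list alone) and adjusted p = 0.3272. Atf4 itself was at 244.5 ± 22.6 CPM in Eif2A and 165 ± 4.00 CPM in TRAP (log2 fold change 0.61 ± 0.26 SE, n = 4 and 5, adjusted p = 0.866). That SE and adjusted p rest on a spread shared by all 29 libraries, not on the SDs of these groups alone. They therefore do not exclude a higher Atf4 level in Eif2A. Homeostatic genes (median 0.03) and disease-associated genes (median 0.16, mean -0.01) gave adjusted p = 0.7515 and 0.5404. No gene passed edgeR's quasi-likelihood test (0 of 16074), also within batch 1, while 912 had an unadjusted p under 0.05. DESeq2 called 255 (138 higher, 117 lower), limma-voom 0, limma-trend on RPKM 0 or 1, and edgeR fitted to the 4 groups without the construct 272, of which 241 were higher. Without Eif2A replicate 3 the number was 1. Within batch 1 the mean level of ribosomal protein genes was 0.51 ± 0.22 in Eif2A and -0.10 ± 0.17 in TRAP (log2 relative to all TRAP, SD, n = 4 each), a difference of 0.60. An exact permutation test gave p = 0.0286, the smallest that 4 against 4 allows, and adjusted p = 0.28 over 42 tests.

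**Figure D4:**
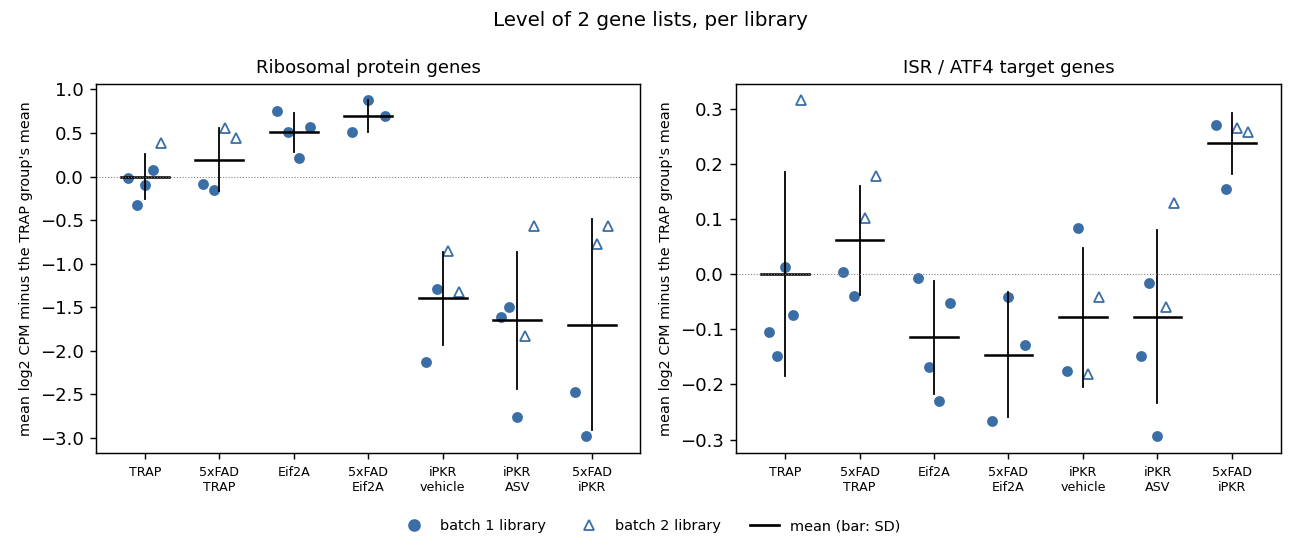
Mean log2 CPM per library, minus the mean of the TRAP group, of ribosomal protein genes (left) and of ATF4 and stress response targets (right); circles are batch 1 and triangles batch 2 libraries, lines are means and bars SD. For ribosomal protein genes the Eif2A mean lies at 0.51 and the 5xFAD Eif2A mean at 0.69, and for ATF4 targets iPKR vehicle and iPKR ASV lie at -0.08 each.

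In 5xFAD mice, Eif2A was compared with the plain tag, and here the 5xFAD TRAP mice alone had VEGF and ASV. Ribosomal protein genes rose in 2 of 74 members (31 over the list alone), with a median of 0.92 and all 74 positive. The 5xFAD TRAP libraries parted by batch, at levels of -0.08 and -0.15 in batch 1 and 0.56 and 0.44 in batch 2, against 0.51, 0.87 and 0.69 in 5xFAD Eif2A, and without batch in the model the median was 0.43. Rpl17 rose from 50.5 ± 40.4 to 89.8 ± 17.4 CPM (SD, n = 4 and 3; log2 fold change with batch and sex in the model 2.23 ± 0.42 SE, adjusted p = 0.02904). Oxidative phosphorylation genes had a median of 0.62 with 0 of 69 called (4 higher over the list alone), and 0.30 without batch in the model. The disease-associated list had a median of 0.72, with 26 of 29 positive and 0 called (0 over the list alone, median 0.38 within batch 1), and the interferon list 0.88, with 0 of 19 called (0 over the list alone), where 5xFAD TRAP replicate 4 lay at 2.62, above the 1.77, 1.67 and 2.16 of 5xFAD Eif2A. Mctp1, which encodes a calcium-binding membrane protein, fell from 65.8 ± 14.0 to 15.02 ± 4.37 CPM (log2 fold change -2.32 ± 0.36 SE, adjusted p = 0.006239). Neuron markers fell in 1 of 13 members (8 over the list alone), with a median of -0.82, the member being the GABA synthesis gene Gad2 (-2.66 ± 0.51). Here 5xFAD TRAP replicates 1 and 2 stood apart with neuron marker levels of 0.87 and 0.38, against 0.18 and 0.13 in replicates 3 and 4 and -0.07, -0.76 and -0.02 in 5xFAD Eif2A. Camera called the ribosomal (adjusted p = 3.834e-35), oxidative phosphorylation (1.368e-13), disease-associated (3.566e-08), interferon (7.122e-05) and neuron lists (3.702e-09), each with adjusted p = 0.3159 with an estimated correlation. The tRNA synthetases were lower (median -0.44, 0 of 13 positive, 0 called, 0 over the list alone, adjusted p = 0.00159), with adjusted p = 0.4502 with an estimated correlation and a median of 0.05 without batch in the model.

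The ATF4 targets had a median of -0.02 between the 5xFAD groups (adjusted p = 0.4054), with 0 of 31 called (2 lower over the list alone), and Eif2s1 changed by 0.07 ± 0.27 without passing. In all 27 genes changed, 7 higher and 20 lower, and 24 with batch 1 alone, in which all 5xFAD Eif2A libraries fall. Leaving out 5xFAD TRAP replicates 1 to 4 gave 5, 5, 4 and 4 genes, and leaving out 5xFAD Eif2A replicates 1 to 3 gave 8, 2 and 2. Mctp1 lost its call without 5xFAD Eif2A replicate 2 (adjusted p = 0.123), Rpl17 without any 1 of 6 of the 7 libraries (highest adjusted p = 0.212) and Gad2 without any of the 7 (highest adjusted p = 0.232). With batch left out of the model no gene passed in edgeR (0), and DESeq2 called 485, of which 187 were higher. The number was 1095 with only these 2 groups in the model, 586 with the 4 groups without iPKR and 8 with sex taken from Y-linked reads.

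The effect of the drug that acts on iPKR was asked by comparing iPKR ASV with iPKR vehicle, whose tag-bound RNA held only 0.605% and 0.513% of counts in homeostatic microglial genes against 6.18% in TRAP. In this RNA, which cannot be taken as microglial alone, the ATF4 targets did not pass as a list, with a median log2 fold change of -0.04, 15 of 31 positive, 0 called (0 over the list alone) and adjusted p = 0.9342. Eif2s1 (0.25 ± 0.23), Eif2ak2, the mouse gene of PKR (0.10 ± 0.81), and the tagged ribosomal gene Rpl10a (-0.12 ± 0.37) did not pass. Interferon response genes stood higher as a list, with a median of 0.81, 17 of 19 positive, and 1 called (2 over the list alone), the RNA sensor gene Ddx58. It rose from 0.705 ± 0.130 to 6.73 ± 4.39 CPM (SD, n = 4 and 5; log2 fold change 3.26 ± 0.52 SE, adjusted p = 0.005134). In iPKR vehicle replicates 1 to 4 a count of 3 equals 1.033, 0.094, 0.796 and 0.424 CPM (not TMM-scaled). Apart from replicate 2, the Ddx58 level in iPKR vehicle thus lay near the counting floor, and the size of its fold change is uncertain. Endothelial markers had a median of 1.95 with 0 of 11 called (5 higher over the list alone), and immediate-early genes -0.71 with 1 of 17 called lower (6 over the list alone). The endothelial share of counts was uneven in iPKR ASV, from 0.0041% to 0.0464%, against 0.0051% to 0.0074% in iPKR vehicle. The tRNA synthetases had a median of 0.27, with 0 of 13 called (0 over the list alone). Camera gave adjusted p = 2.054e-05 for interferon, 2.054e-05 for endothelial markers, 6.503e-05 for immediate-early genes and 0.0437 for tRNA synthetases. With an estimated correlation all were lost (adjusted p = 0.4456, adjusted p = 0.2654, adjusted p = 0.2654 and adjusted p = 0.8192). The 5 markers of monocytes and neutrophils had a median of 2.16 with 0 called (2 higher over the list alone) and adjusted p = 0.04843, and adjusted p = 0.4456 with an estimated correlation.

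Among single genes, Prpf8 rose from 156.9 ± 138 to 633.9 ± 419 CPM (log2 fold change 2.15 ± 0.31 SE, n = 4 and 5, adjusted p = 0.003282), and the ubiquitin ligase gene Ubr3 rose by 3.11 ± 0.48. The transcription factor gene Nfil3 fell from 23.8 ± 3.99 to 7.97 ± 0.733 CPM (log2 fold change -1.58 ± 0.27 SE, adjusted p = 0.01048). In all 68 genes changed, 51 higher and 17 lower, with 314 in batch 1 alone (153 higher), 23 in batch 2 alone and 0 with only these 2 groups in edgeR's model, while DESeq2 called 589. With sex taken from Y-linked reads, which contradict the label of 4 of the 5 iPKR ASV libraries, the number was 14. The number was 10 without iPKR ASV replicate 4, 44 without iPKR ASV replicate 1, 179 without iPKR ASV replicate 2, and 33, 19 and 34 without iPKR vehicle replicates 1, 2 and 4. Without the 3 libraries richest in neuron markers it was 284, and the tRNA synthetase list then had a median of 0.08 with adjusted p = 0.253. That list also lost its call without iPKR vehicle replicate 1 (0.15, adjusted p = 0.156), iPKR vehicle replicate 2 (0.12, adjusted p = 0.356) or iPKR ASV replicate 3 (0.06, adjusted p = 0.403).

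In mice with 5xFAD that all had VEGF and ASV, those with the iPKR construct were compared with those with the plain tag. Homeostatic genes took 5.48% of counts in 5xFAD TRAP and 1.11% in 5xFAD iPKR. The RNA of 5xFAD iPKR cannot be taken as microglial alone. A lower share of microglial RNA was not told apart from an effect of iPKR within microglia. Disease-associated genes fell in 22 of 29 members (22 over the list alone), with a median log2 fold change of -1.96, and all 19 homeostatic genes fell (19), with a median of -2.62. Neuron markers rose in 13 of 13 (13 over the list alone), with a median of 2.38, astrocyte markers in 9 of 10 (9) and oligodendrocyte markers in 11 of 12 (11, with 1 lower). The protease gene Ctsd fell from 3988 ± 528 to 739.5 ± 359 CPM (SD, n = 4 each; log2 fold change -2.60 ± 0.33 SE, adjusted p = 8.04e-07), and Rbfox3 rose by 2.11 ± 0.22. ATF4 targets went both ways, with 11 of 31 higher and 8 lower (11 and 9 over the list alone) and a median of -0.04 (mean 0.30, adjusted p = 0.8116). Among them the asparagine synthetase gene Asns rose by 2.64 ± 0.51 and the transcription factor gene Cebpb fell by 2.35 on the log2 scale. Of the targeted genes Thy1 rose by 3.15 ± 0.55 and App by 2.28 ± 0.56, while Cx3cr1 fell by 2.87 and Eif2s1 by 0.86 on the log2 scale. All 7 mitochondrially encoded genes rose (7 over the list alone), with a median of 2.55 and adjusted p = 0.0007429 (adjusted p = 0.236 with an estimated correlation). The 5xFAD iPKR libraries parted by batch, with neuron levels of 3.27 and 3.63 in batch 1 and 1.87 and 2.05 in batch 2, mitochondrial levels of 0.11 and 0.04 against 3.37 and 4.08, and ribosomal levels of -2.47 and -2.98 against -0.78 and -0.56. App parted in the same way, at 3868 and 4665 CPM in batch 1 and 511 and 355 CPM in batch 2, and its call was lost without 5xFAD iPKR replicate 2 (adjusted p = 0.0528). In all 7704 genes changed, 4015 higher and 3689 lower, with 6430 in batch 1 alone and 4395 in batch 2 alone. Camera called the disease-associated, homeostatic and neuron lists (adjusted p = 3.51e-08, 1.109e-12 and 1.378e-08), each with adjusted p = 0.111 with an estimated correlation.

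The drug effect without 5xFAD and the construct effect in 5xFAD mice differed in 5973 genes when the difference was tested, 3135 higher and 2838 lower, with 4577 in batch 1 and 2788 in batch 2. The disease-associated list differed by a median of -2.25 with 17 of 29 lower (19 over the list alone, adjusted p = 2.605e-08), and adjusted p = 0.1318 with an estimated correlation. Of the 68 genes changed by ASV in iPKR mice, 29 had the same sign in 5xFAD iPKR against 5xFAD TRAP, with r = 0.097 and rho = 0.031 across genes. The ASV contrast in iPKR mice has the construct on both sides, whereas the 5xFAD contrast has it on 1 side only.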

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

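The tests of other cell types and of VEGF in the construct comparison, the test of other cells for the ribosomal list in 5xFAD mice, the tests of batch for the ribosomal list in 5xFAD mice and for the disease-associated list, the splits with batch kept, the sex taken from Y-linked reads, the thinning to equal depth and the interaction without 2 libraries were chosen after the results were seen.

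Chance flags about 1 in 20 groups, and 126 groups of values were tested, so 6.3 would stand apart by chance; 5 did. The Cx3cr1 level of TRAP replicate 2 was 15.7 CPM against 575.1 for the next library, a gap of 0.815 of the group's range (n = 5). In iPKR ASV, replicate 3 was highest for App (2607 CPM, next 745, gap 0.898 of the range, n = 5) and for Thy1 (189.8 CPM, next 71.9, gap 0.723). The share of neuron markers in Eif2A replicate 3 was highest by 0.927 of the range (n = 4). Total counts of iPKR vehicle replicate 2 were 31.998 M against 7.079 M for the next library, a gap of 0.856 (n = 4).

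Y-linked genes were read at 135.5 CPM or more in libraries taken as male and at 1.74 CPM or less in the others. By these levels, a signal outside the comparisons, 4 libraries labelled female were taken as male and 4 labelled male were taken as female. These 8 are Eif2A replicates 3 and 4, iPKR ASV replicates 1, 3, 4 and 5, and 5xFAD iPKR replicates 1 and 2. The number of males was right in 7 of 7 groups, so each wrong label has a partner within its own group.

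Differences between effects that were tested themselves gave 1 gene for 5xFAD on Eif2A against the plain tag and 5973 genes for the construct in 5xFAD against the drug without 5xFAD. The disease-associated list differed by a median of 0.6237 (camera adjusted p = 1.503e-06) in the first and by -2.251 (camera adjusted p = 2.605e-08) in the second, with adjusted p = 0.22 and adjusted p = 0.1318 with an estimated correlation.

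The first pattern weighed was the wide difference between iPKR vehicle and TRAP. For a lower share of microglial RNA that raised all other cell types alike, marker lists were compared. Neuron markers rose by 0.73 more than oligodendrocyte markers on the log2 scale (95% interval 0.352 to 1.76). The 95% intervals in this section come from resampling the genes of a list, not the mice. They hold no spread between animals, so this one does not decide the question. Depth was argued against by 7963 genes at equal depth, and batch by 8185 genes within batch 1. VEGF with its vehicle as the whole cause was argued against by a homeostatic median of -2.617 (95% interval -2.874 to -2.168) in 5xFAD iPKR against 5xFAD TRAP, where both had them. Between mice, too, the homeostatic share of counts was at least 4.60% in 5xFAD TRAP and at most 1.86% in 5xFAD iPKR. A lower share of microglial RNA stays open, whether other cell types rose alike or in a different mix. The construct itself stays open as well, and these were not tested apart.

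The second pattern weighed was the higher ribosomal protein list with Eif2A. Better recovery of short transcripts as the whole cause was argued against by lists matched for length and expression. Their median was 0.13 in Eif2A against TRAP, where the ribosomal median was 0.70. In 5xFAD Eif2A against 5xFAD TRAP the medians were 0.26 and 0.92. The matched genes rose too, so a part of the rise may go with length. Of 10000 such lists 0% had a median as high in either comparison. They drew unrelated genes, while ribosomal protein genes can move together, so that share is no measure of chance. Less RNA from cells other than microglia was weighed by the homeostatic median, which lay at -0.6758 from the ribosomal median without 5xFAD (95% interval -0.7801 to -0.5434). With 5xFAD it lay at -0.5581 (-0.902 to -0.3042). These intervals hold over the genes of the lists and not over the mice, so less RNA from other cells stays open. An effect of the Eif2s1 genotype may explain the pattern and stays a hypothesis, since the call was lost with an estimated correlation (adjusted p = 0.3434 and adjusted p = 0.3159). In 5xFAD mice the median was 0.8292 within batch 1, a value that does not come from setting batches against each other. That fit rests on replicates 1 and 2 of 5xFAD TRAP, which had the lowest ribosomal and highest neuron marker levels of their group. It therefore cannot tell the genotype from whatever marks these libraries. Batch, neuronal RNA in these libraries and the drug given to 5xFAD TRAP mice stay open there.

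The third pattern weighed was the larger rise of the disease-associated list in 5xFAD on Eif2A. Sex labels that Y-linked reads contradict were argued against by 0.6606 with sex from those reads. Batch stays open, since the difference was 0.3775 (adjusted p = 0.0811) within batch 1 and neither Eif2A group has a batch 2 library. Neuronal RNA in 5xFAD TRAP replicates 1 and 2 stays open too, since the difference of 1.301 without them sets batch 2 libraries alone against batch 1. The drug given to 5xFAD TRAP mice only cannot be told apart from the genotype, since 0 libraries of that group were without it, and the call was lost with an estimated correlation (adjusted p = 0.22).

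Other splits of the libraries, the real one included, were refitted for each count, and again with each group's number of batch 2 libraries kept. For 5xFAD TRAP against TRAP 1 of 60 splits gave as many genes as the real one (127, highest other 31), and 1 of 45 with batch kept (highest other 2). For 5xFAD Eif2A against Eif2A 1 of 35 gave as many (499, highest other 119), all in batch 1. For iPKR vehicle against TRAP 1 of 60 gave as many (8695, highest other 6368), and 1 of 45 with batch kept (highest other 1477). For the construct and drug difference 1 of 40 gave as many (5973, highest other 4691), and 1 of 40 with batch kept (highest other 5097). In these 4 the real split gave the most genes of the splits run, a share under 0.05 that was not adjusted over the comparisons. The high other splits of the last 2 point to the construct as a structure of the samples. The split with 5097 genes kept the 5xFAD iPKR and 5xFAD TRAP groups as they were and regrouped only ASV and vehicle mice. For that last count the splits therefore say little about the difference between the effects.

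For 5xFAD iPKR against 5xFAD TRAP 1 of 35 splits gave as many genes (7704, highest other 48), and for 5xFAD Eif2A against 5xFAD TRAP 1 of 35 (27, highest other 0). The splits that keep batch number 18 (highest other 1) and 10 (highest other 0) there, too few for a share under 0.05.

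Chance cannot be excluded for iPKR ASV against iPKR vehicle, where 5 of 60 splits gave as many genes (68, highest other 1464), and 3 of 60 with batch kept (highest other 392). The split with 1464 set the 4 batch 2 libraries with iPKR ASV replicate 3 against the other 4 libraries. That points to a structure of the samples. Batch and that replicate, which stood apart for App and Thy1, cannot be told apart in this split, and batch 1 alone gave 314 genes. Nor can it be excluded for 5xFAD iPKR against iPKR ASV, where 5 of 60 gave as many (277, highest other 1592), and 6 of 60 with batch kept. The split with 1592 set iPKR ASV replicates 1, 2 and 5 with 5xFAD iPKR replicate 4 against the rest, which hold the 3 libraries richest in neuron markers, again a structure of the samples. For the 5xFAD effect on Eif2A against the plain tag 4 of 40 gave as many (1, highest other 2), and 7 of 40 with batch kept (highest other 3), so chance cannot be excluded there. For Eif2A against TRAP the splits decide nothing, since any of the 60 gives at least the real 0 of edgeR (highest other 2, with 912 genes at an unadjusted p under 0.05 and 255 by DESeq2).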

How the results depend on the processing

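Sex from Y-linked reads, batch 2 alone, the fit without 3 neuron-rich libraries, the 4 groups without iPKR, equal depth and the interaction without 2 libraries were chosen after the data were seen. No named gene reversed under any alternative. The cause was not tested for the changes below. Fits with fewer libraries have fewer samples, but that alone cannot raise a count, as in the listed fits to the 4 groups without iPKR. Within iPKR mice the counts fell with only the groups compared in the model. The model assumes a spread per gene shared by all groups. Whether this makes the main counts too low without iPKR and too high within iPKR mice was not tested.

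Genes for iPKR ASV against vehicle (68) numbered 32 with no low-count filter, 20 with no batch, 26 with neither batch nor sex, 314 in batch 1, 23 in batch 2, 14 with sex from Y-linked reads, 284 without the 3 neuron-rich libraries and 440 with limma-voom. They numbered 231 on RPKM + 1, 589 with DESeq2 and 0 in edgeR with only the groups compared. For 5xFAD TRAP against TRAP (127) they were 75 with neither covariate, 249 without the 3 libraries, 958 with 4 groups, 749 with only the groups compared and 729 with DESeq2. For Eif2A against TRAP (0 in edgeR, 912 at an unadjusted p under 0.05) they were 272 with 4 groups, 1 on RPKM + 1 and 255 with DESeq2.

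For 5xFAD Eif2A against 5xFAD TRAP (27) they were 15 with RLE factors, 12 with no low-count filter, 14 with no sex, 0 with no batch, 0 with neither, 8 with sex from Y-linked reads, 94 without the 3 libraries, 586 with 4 groups, 1095 with only the groups compared, 6 with limma-voom, 15 on RPKM + 0.1 and 485 with DESeq2. For 5xFAD Eif2A against Eif2A (499) they were 329 with no batch, 308 with neither, 898 without the 3 libraries, 2090 with 4 groups, 1664 with only the groups compared and 1277 with DESeq2. For 5xFAD iPKR against iPKR ASV (277) they were 184 with no batch, 454 in batch 1, 124 in batch 2, 739 without the 3 libraries, 10 with only the groups compared and 845 with DESeq2. For 5xFAD iPKR against 5xFAD TRAP batch 2 gave 4395 (7704), and for the construct and drug difference 2788 (5973). The 5xFAD effects on Eif2A and the plain tag differed in 3 genes with no sex, 0 with no batch, 0 with neither, 2 in batch 1, 3 with sex from Y-linked reads, 3 without the 3 libraries, 42 with 4 groups, 42 with only the groups compared, 0 without 5xFAD TRAP replicates 1 and 2, 0 on RPKM + 0.1 and 267 with DESeq2 (1).

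The replicate numbers do not pair the libraries, and with a replicate block the counts were 5 for iPKR ASV, 76 for 5xFAD TRAP, 4 for 5xFAD Eif2A against 5xFAD TRAP and 135 for 5xFAD iPKR against iPKR ASV.

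Leaving out each library in turn gave 10 to 179 genes for iPKR ASV against vehicle, 53 to 122 for 5xFAD TRAP, 0 to 1 for Eif2A, 2 to 8 for 5xFAD Eif2A against 5xFAD TRAP, 222 to 419 for 5xFAD Eif2A against Eif2A, 172 to 542 for 5xFAD iPKR against iPKR ASV and 0 to 3 for the difference of 5xFAD effects. It gave 6881 to 7402 for 5xFAD iPKR against 5xFAD TRAP, 8081 to 8543 for iPKR vehicle and 5408 to 6132 for the construct and drug difference.

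The disease-associated list lost its call with an estimated correlation for 5xFAD iPKR against 5xFAD TRAP (-1.96, adjusted p = 0.111) and for 5xFAD Eif2A against 5xFAD TRAP (0.72, adjusted p = 0.316), the latter also with fry (adjusted p = 0.145). It kept its call under every alternative run in the 3 comparisons of 5xFAD, with medians of 1.80 to 2.21, 2.80 to 2.99 and 1.98 to 2.68 when libraries were left out. The ATF4 list passed in none of the alternatives run for iPKR ASV against vehicle (-0.12 to 0.09 when libraries were left out) and Eif2A against TRAP (-0.23 to -0.04). The tRNA synthetases in 5xFAD Eif2A against 5xFAD TRAP turned from -0.44 to 0.053 with no batch (adjusted p = 0.898) and to 0.051 with neither batch nor sex (adjusted p = 0.947).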
